A study of Neotoma lepida with 16 samples.

How the data were processed

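Total RNA from the livers of 16 desert woodrats was converted to Cy3-labelled cRNA and hybridised to 1-colour Agilent arrays, 1 sample per array, per the labels' protocols. The series design gives 4 individuals per group, so arrays are taken as separate animals. The arrays were read with Agilent Feature Extraction 9.1, per the submitters' processing notes. The deposited table holds 1 value per probe and array, used here as log2 intensity. The log base is not given in the sources used here and was taken from the range of the deposited values, 1.43 to 18.6, which as powers of 2 span a scanner's range of intensities. The background correction, any scaling between arrays, the quality flags and the slide of each array are not given in the sources used here. Scanner output and flags for probes above background were not used here, so whether a dim probe was detected could not be decided per array. No batch could therefore be tested. If slides or hybridisation runs coincided with temperature or diet, their effects and those of the treatments could not be told apart in any comparison here.

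The table held 6286 probe IDs and 4 missing values in 3 probes. The IDs fall into 4 sets by their ending, of 2389, 2076, 940 and 881 probes. No table pairing IDs with genes was used here, so 47 lists of genes fixed before the data were examined, markers of other liver cell types among them, could not be applied and gave no result. The medians of the deposited columns ran from 9.38 to 10.1. Because that span, 0.755, was over 0.25, the limit set before the data were examined, the arrays were not treated as already scaled. From each array its 75th percentile was subtracted (11.475 to 12.176 as deposited), and the mean of the 75th percentiles, 11.9, was added back. Values on this scale are called scaled log2 intensities. Whether the deposited values had been scaled in another way stays unknown.

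Probes were tested with limma 3.58.1 in R 4.3.3. A linear model with a mean for each of the 4 groups and a term for sex was fitted to all 16 arrays, which share 1 estimate of the spread per probe, followed by empirical Bayes moderation. A probe was tested where every group had at least 3 values, which left out 1 probe and kept 6285. The contrasts were diet at each temperature, temperature on each diet, the mean of each pair, the interaction, and sex. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and a probe was called at an adjusted p under 0.05. Fold changes are creosote minus control diet, warm minus cool, and female minus male. The p-values of probes are those of limma throughout.

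By a rule fixed before the data were examined, up to 2 called probes with the highest and 2 with the lowest fold change were named per contrast. Where fewer than 5 probes were called, up to 2 higher and 2 lower among the 5 smallest p-values were named as values only. Where a named probe came within 0.5 of the floor of an array, a limit set after the data were seen, its p is given and the size of its change is not. The share of the variance over all probes that lies between groups was tested by exact enumeration of the group labels, 70 arrangements for 4 against 4 arrays and 4900 for a factor averaged over the other, a measure chosen after the data were seen. The correlation of fold changes between separate sets of animals used the same 4900 arrangements.

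The model was tested on simulated data for diet in the cool, with the means and spreads of 6283 probes without missing values and 200 probes changed in each of 10 simulations. It recovered 62.5% of probes changed by 1 on the log2 scale and 91.1% of those changed by 2, with 4.77% wrong calls and 0 calls in the unchanged comparison. The simulated noise was independent between probes and had no array floor. These rates therefore do not cover probes that move together across arrays.

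Alternatives chosen before the data were examined were to leave out the sex term, use the replicate number as a block, normalize by quantiles, use the values as deposited, leave out the dimmest 25% of probes by mean over all arrays, use a trended and robust prior, weight arrays by quality, fit only the groups compared, and leave out each array in turn. Alternatives added after the data were seen were to set scaled values under 5 or under 6 to that level and test probes above it on at least 4 arrays, to add a constant to each array so that the 20th percentiles agreed, with and without the dimmest 25%, to combine quantile normalization with leaving out the dimmest 25%, to use the floor as a covariate, and to leave out the 2 arrays with the highest floor. Averaging the probes of a gene needs gene names and was not run.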

Results

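Liver RNA of 16 desert woodrats (Neotoma lepida, a herbivorous rodent of the deserts of western North America) was measured on 1-colour Agilent arrays, 1 array per animal. The animals formed 4 groups of 4, each with 2 females and 2 males. They had been kept at 22 or 27 °C for at least 14 days and were then fed a control diet or a diet with creosote for 8 days; creosote bush is a desert shrub whose leaves carry a phenolic resin. The 22 °C groups are called cool and the 27 °C groups warm. The design asks how ambient temperature and a diet with plant toxins, alone and together, change gene expression in the liver. The value table held 6286 probes with a log2 intensity for each array. It does not pair the probe IDs with gene names, so probes are named by ID, and the lists of genes fixed beforehand could not be applied. The number of arrays, 4 per group, limits the precision of every comparison.

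The arrays were similar to one another, with correlations of 0.9721 to 0.9903 between pairs over all probes, and no pair of columns was identical. They differed at the low end of the scale. After scaling, the lowest value of an array, called its floor here, averaged 3.35 ± 0.497 (SD, n = 4) in cool animals on creosote, against 1.70 ± 0.469 (SD, n = 4) in cool controls, 1.91 ± 0.531 (SD, n = 4) in warm controls and 2.47 ± 0.420 (SD, n = 4) in warm animals on creosote. The floors of cool creosote and cool control arrays did not overlap (exact two-sided permutation test, p = 0.0286, the smallest these 4 against 4 arrays can give; Benjamini-Hochberg adjusted p = 0.0858 over the 6 pairs of groups). Many of the probes that passed the tests lay close to this floor. Each comparison is therefore given for all probes and again for the 4713 brighter probes, those left when the dimmest 25% of probes, with a mean scaled level under 6.87, were not tested.

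**Figure D1:**
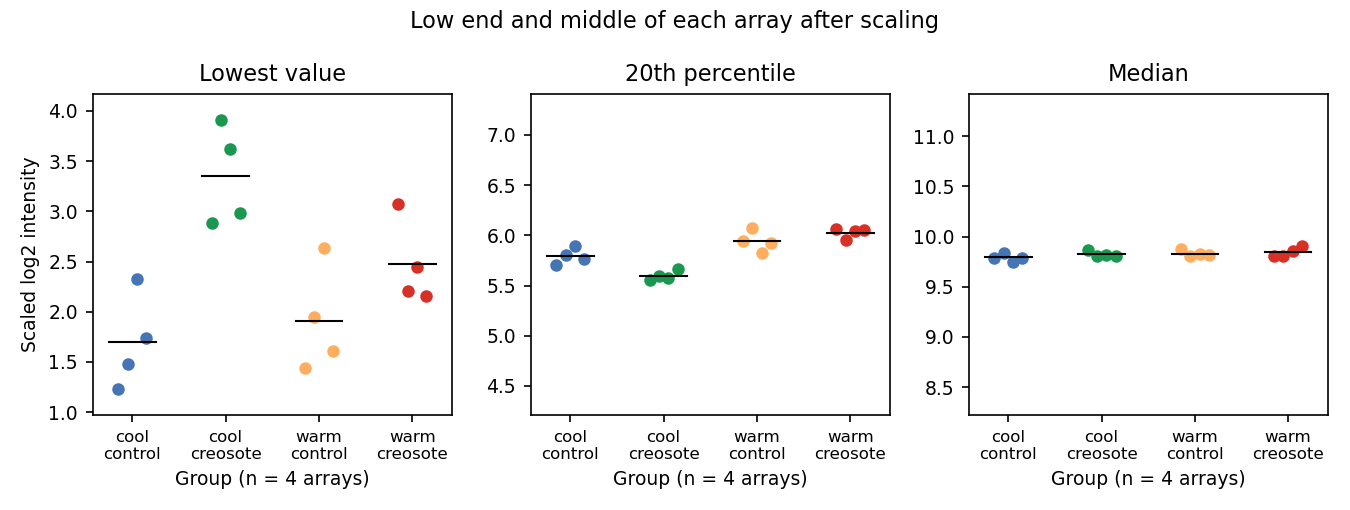
Lowest value, 20th percentile and median of each array on the scaled log2 intensity scale, by group, with 4 points per group for the 4 arrays and a horizontal line for the group mean. The lowest values of cool creosote arrays averaged 3.35 and those of cool controls 1.70, while the medians of all 16 arrays lay within 0.156 of each other.

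Averaged over both diets, a small set of probes outside the dim range differed with temperature. Among the 4713 brighter probes, 14 were higher and 3 lower at 27 °C than at 22 °C (limma, Benjamini-Hochberg adjusted p under 0.05), with log2 fold changes from -0.71 to 1.99 and a median size of 0.69. All 17 had the same direction on both diets, and 14 were larger on creosote (median sizes 0.906 there and 0.589 on the control diet). With background levels aligned, 5 of these 17 remained called. Another split of the same arrays into groups of the same sizes called 44 brighter probes. Probe CUST_675_PI426395977 rose 3.97-fold in the warm (log2 fold change 1.99, SE 0.248, limma adjusted p = 0.00114 over all probes and 0.00288 among the brighter ones, 0.000788 to 0.0112 over 14 alternative settings), from means of 6.57 ± 0.742 and 5.54 ± 0.371 (SD, n = 4 each) in cool control and cool creosote animals to 7.75 ± 0.280 and 8.34 ± 0.641 (SD, n = 4 each) in warm ones. Probe CUST_1141_PI426383273 fell by 0.68 on the log2 scale (SE 0.116, limma adjusted p = 0.0115 over all probes and 0.025 among the brighter ones, 0.00104 to 0.0378 over the settings). Its means were 10.78 ± 0.155 and 10.42 ± 0.289 (SD, n = 4 each) in cool and warm controls, whose arrays overlapped. On creosote they were 11.06 ± 0.268 and 10.06 ± 0.164 (SD, n = 4 each). The difference between the diets was not called (limma interaction, adjusted p = 0.492). Probe CUST_1115_PI426383273, with a mean level of 13.7, fell by 0.71 (SE 0.134, limma adjusted p = 0.0173 over all probes and 0.044 among the brighter ones) and passed in 10 of 14 alternative settings (limma adjusted p 0.00208 to 0.0628).

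Over all 6285 probes tested, the same comparison called 156 probes, 141 higher and 15 lower in the warm (55 to 213 calls when each array was left out in turn). Of the 156, 106 lay in the dimmest 25%, and 105 of those 106 were higher. One of them, probe CUST_312_PI426386924, rose 3.08-fold (log2 fold change 1.62, SE 0.177, limma adjusted p = 0.00061), with means of 5.73 ± 0.247 and 5.27 ± 0.539 (SD, n = 4 each) in cool control and cool creosote animals and 7.003 ± 0.333 and 7.24 ± 0.365 (SD, n = 4 each) in warm ones. The scaled 20th percentiles of the arrays were also higher in the warm. On creosote they were 5.95 to 6.06 in warm and 5.55 to 5.66 in cool arrays, without overlap. On the control diet they were 5.82 to 6.07 and 5.71 to 5.89. In the averaged comparison, 61.1% of the dimmest 25% of probes had a positive fold change. Whether background or RNA raised dim probes as a set could not be told. Quantile normalization left 36 calls, 26 higher and 10 lower, and the values as deposited 17 higher and 1 lower. Aligning the background levels gave 141 higher and 761 lower. That setting added unlogged constants of 16.5 to 20.1 to cool creosote arrays and 0.3 to 5.2 to warm creosote arrays. Larger constants in the cool by themselves lower dim probes in the warm, so the 761 do not speak on direction. The balance of directions over all probes thus varied with the scaling, here in part by construction. Of the 17 brighter probes, 5 remained called when all probes were quantile normalized and the dimmest 25% then left out. In all 15 settings of the fit, and also without any single array, 4 probes were called. Besides CUST_675_PI426395977 and CUST_1141_PI426383273, these were CUST_190_PI426395977 (log2 fold change 1.504) and CUST_1693_PI426384047 (0.98), both singled out after their values were seen. Dim probes could not be among the 4, since some settings leave them out. CUST_312_PI426386924 passed in all 11 alternative settings that tested it (limma adjusted p 0.000163 to 0.00439).

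Temperature was next compared within each diet. In animals on creosote, 6 of the brighter probes rose and 1 fell in the warm, and all 7 are among the 17 of the averaged comparison, which contains this one. Their log2 fold changes ran from -0.996 to 2.80. With quantile normalization of the brighter probes 2 were called, 1 higher and 1 lower. CUST_675_PI426395977 was 6.97-fold higher in warm than in cool animals on creosote (log2 fold change 2.80, SE 0.351, limma adjusted p = 0.00311 over all probes and 0.00684 among the brighter ones) and passed in 14 of 15 alternative settings (limma adjusted p 0.000403 to 0.0801). Probe CUST_9_PI426395977 is not one of the 7: it was called only over all probes, where it was 4.50-fold lower (log2 fold change -2.17, SE 0.538, limma adjusted p = 0.0484; 0.111 among the brighter ones), at 8.10 ± 0.918 (SD, n = 4) against 10.3 ± 0.944 (SD, n = 4), and it passed in 3 of 15 alternative settings, with limma adjusted p from 0.0122 to 0.215.

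Over all probes, 173 were called on creosote, 151 higher and 22 lower in the warm, 129 of them in the dimmest 25%. Leaving out each array in turn gave 57 to 296 calls. Quantile normalization gave 41 higher and 55 lower, and the values as deposited 57 and 22, so here too the balance of directions depended on the scaling. Aligned background levels gave 97 and 742, but their larger constants in the cool creosote arrays by themselves lower dim probes in the warm. The dim probe CUST_213_PI426386924 was called as higher in the warm (limma adjusted p = 0.0291; 5 of 12 alternative settings), with cool creosote values 0.28 to 1.37 above the floors of their arrays. CUST_306_PI426386924 was called as lower (limma adjusted p = 0.0475; 5 of 10 alternative settings), with warm creosote values 0.22 to 0.32 above the floors. So close to the floor, the sizes of these changes are not given. With only the 8 creosote arrays in the fit, limma called 0 probes, with 1010 at an unadjusted p under 0.05.

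On the control diet no probe passed the threshold for temperature in limma, neither over all probes (smallest adjusted p = 0.088) nor among the brighter ones (323 at an unadjusted p under 0.05). Over all probes, at an unadjusted p under 0.05 there were 414 probes, where 314 would be expected by chance. The smallest p-values belonged to CUST_190_PI426395977 and CUST_191_PI426395977, both with a limma adjusted p of 0.088. The log2 fold change of CUST_190_PI426395977 was 1.499 (SE 0.241), from 6.61 ± 0.336 in cool to 8.11 ± 0.465 in warm controls (SD, n = 4 each). It passed in 1 of 15 alternative settings (limma adjusted p 0.0258 to 0.258). The log2 fold change of CUST_191_PI426395977 was 1.30 (SE 0.211). In the other direction, CUST_2161_PI426383273 and CUST_1115_PI426383273 had values of -0.97 (SE 0.180) and -0.99 (SE 0.189), both with a limma adjusted p of 0.136. The fold change of CUST_190_PI426395977 on creosote differed from that on the control diet by 0.01 on the log2 scale (limma interaction, adjusted p = 0.998).

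**Figure D2:**
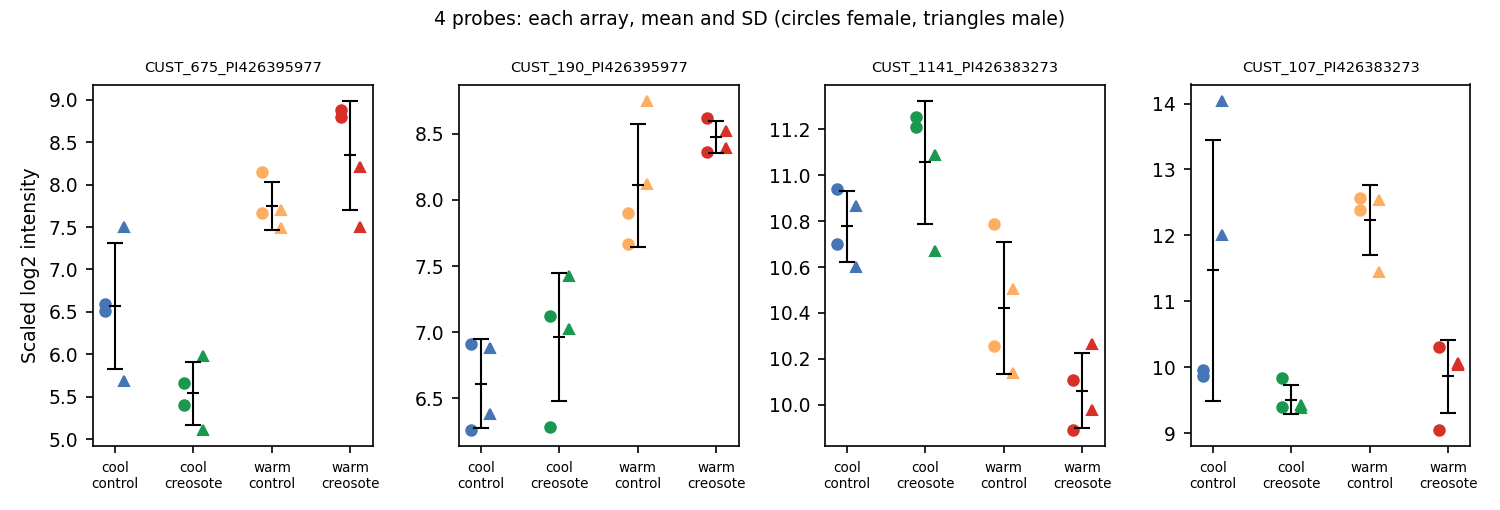
Scaled log2 intensity of 4 probes in each of the 16 arrays by group, with circles for females, triangles for males, and black bars for the group mean and SD (n = 4). By group means, CUST_675_PI426395977 and CUST_190_PI426395977 lay higher and CUST_1141_PI426383273 lower in warm groups. The means of CUST_107_PI426383273 were lower on creosote, with a wide spread in cool controls (SD 1.98), where the females lay near the creosote arrays.

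The creosote diet was compared with the control diet at each temperature. In the cool, 274 probes were called over all probes, 236 higher and 38 lower on creosote; quantile normalization gave 60 and 24, and the values as deposited 194 and 83. They were almost all dim: 244 lay in the dimmest 25%, 221 of them higher, and the median level of the called probes was 2.79, close to the array floors, which were higher in the cool creosote arrays. When the dimmest 25% of probes were not tested, limma called none of the 4713 others, with 391 at an unadjusted p under 0.05 and 236 expected by chance. Both named probes called as higher on creosote lay near the floor: the cool control values of CUST_742_PI426395977 (limma adjusted p = 0.0162) were 0.17 to 0.20 above the floors of their arrays and its creosote values 0.18 to 3.74 above, and CUST_106_PI426384047 (limma adjusted p = 0.0355) came within 0.26 and 0.15 of the floor on the control diet and on creosote. The sizes of their changes are therefore not given. The lowest fold changes among the called probes were those of CUST_760_PI426395977 (log2 fold change -1.71, SE 0.396, limma adjusted p = 0.0269), which passed in 5 of 12 alternative settings (log2 fold change -1.85 to -1.03, limma adjusted p 0.0188 to 0.872), and CUST_462_PI426383273, the only 1 of the 4 outside the dimmest 25%, which was 3.06-fold lower on creosote (log2 fold change -1.62, SE 0.397, limma adjusted p = 0.0355; 7.39 ± 0.150 against 9.003 ± 0.807, SD, n = 4 each) and passed in 4 of 15 alternative settings (limma adjusted p 0.0182 to 0.470). Leaving out cool creosote replicate 2, the array with the highest floor, left 0 calls over all probes, with 807 at an unadjusted p under 0.05.

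**Figure D3:**
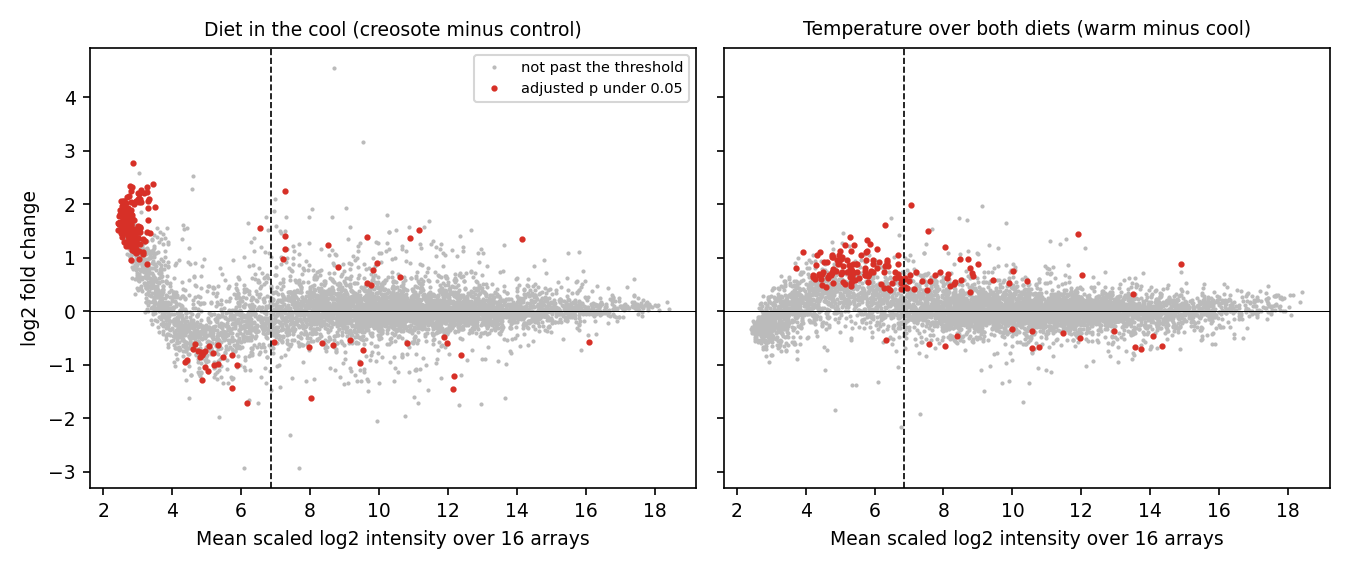
log2 fold change of each probe against its mean scaled log2 intensity over the 16 arrays, for diet in the cool (left) and for temperature over both diets (right), with probes at an adjusted p under 0.05 in red and a dashed line at the edge of the dimmest 25% of probes, 6.87. Of the 274 red points on the left, 244 lie below the line, and of the 156 on the right, 106.

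In the warm, limma called no probe for diet, over all probes (smallest adjusted p = 0.853, 356 probes at an unadjusted p under 0.05) or among the brighter ones (225 at an unadjusted p under 0.05). The smallest p-values among higher and lower probes belonged to CUST_275_PI426395977, whose control values lay 0.17 to 0.78 above the floors of their arrays, to CUST_682_PI426383273 (log2 fold change 0.58, SE 0.133; 13.1 ± 0.192 on creosote and 12.5 ± 0.167 on the control diet, SD, n = 4 each) and to CUST_1644_PI426384047 (-0.78, SE 0.158; 11.7 ± 0.166 against 12.5 ± 0.169, SD, n = 4 each), all with a limma adjusted p of 0.853.

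Averaged over both temperatures, diet called 217 probes, 195 higher and 22 lower on creosote, of which 192 lay in the dimmest 25%. Quantile normalization gave 3 higher and 9 lower, and the values as deposited 119 and 49. Limma called none of the brighter probes when these were tested alone, with 416 at an unadjusted p under 0.05, and none over all probes without cool control replicate 2, with 778 at an unadjusted p under 0.05. The lowest fold change among the called probes belonged to a bright one, CUST_107_PI426383273, which was 4.48-fold lower on creosote over all probes tested (log2 fold change -2.16, SE 0.468, limma adjusted p = 0.0219). Its means were 11.47 ± 1.98 and 12.23 ± 0.527 (SD, n = 4 each) in cool and warm controls and 9.51 ± 0.219 and 9.86 ± 0.554 (SD, n = 4 each) in cool and warm animals on creosote. In cool controls the females were at 9.957 and 9.873 and the males at 12.008 and 14.04. Cool creosote animals were at 9.377 to 9.836, so the difference in the cool came mainly from the male controls. In the warm, controls were at 11.449 to 12.561 and creosote animals at 9.054 to 10.304. CUST_107_PI426383273 passed in 5 of 14 alternative settings, with limma adjusted p from 0.0234 to 0.755. CUST_800_PI426384047 had a similar pattern at a dimmer level (log2 fold change -2.11, SE 0.516, limma adjusted p = 0.0388) and passed in 3 of 11 settings. The 2 named probes called as higher, CUST_106_PI426384047 and CUST_215_PI426384047, both with a limma adjusted p of 0.0219, had means between 2.28 and 2.64 on the control diet, near the floor, and the sizes of their changes are not given.

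Whether the effect of diet differed between the temperatures was tested with the interaction. Limma called no probe (smallest adjusted p = 0.462), with 526 at an unadjusted p under 0.05 over all probes, where 314 would be expected by chance, and 220 among the brighter ones, where 236 would be. With background levels aligned, 5 probes were called, and 0 when the dimmest 25% were also left out (216 at an unadjusted p under 0.05). All 5 were lower. That setting added unlogged constants of 16.5 to 20.1 to cool creosote arrays and 0 to 14.8 to the others. These constants by themselves push the interactions of dim probes down, so the 5 are not read as a difference. Effects called at one temperature or on one diet and not on the other were therefore not shown to differ. The smallest p-values belonged to 3 dim probes, CUST_455_PI426384047, CUST_1555_PI426383273 and CUST_97_PI426395977, all with a limma adjusted p of 0.462. The first came within 0.36 of the floor in cool creosote animals and the others within 0.28 in every group, so no sizes are given.

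Over all probes at once, shares of the variance between arrays lay between groups. Any split of the arrays takes some share, so each is read with its permutation p and not by its size. The shares averaged over a factor are of the variance within its levels, so they are not comparable with the others. Diet accounted for 30.7% in the cool (exact permutation test, p = 0.0286, the smallest that 4 against 4 arrays can give; adjusted p = 0.0429 over 6 comparisons) and for 15.5% in the warm (exact p = 0.229). Temperature accounted for 23.5% on creosote (exact p = 0.0286, adjusted p = 0.0429) and for 16.7% on the control diet (exact p = 0.171). Averaged over the other factor, diet accounted for 15.3% (exact p = 0.00163, adjusted p = 0.0098) and temperature for 11.996% (exact p = 0.00408, adjusted p = 0.0123). Without the dimmest 25% of probes, these shares were 9.59% for diet (exact p = 0.0661, adjusted p = 0.132) and 10.8% for temperature (exact p = 0.018, adjusted p = 0.108), and no comparison passed after adjustment.

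The effects of one factor were also compared between the levels of the other, which use different animals. Across the brighter probes, the fold changes for temperature on the control diet and on creosote had a correlation of 0.207 (exact one-sided permutation test, p = 0.0755; adjusted p = 0.151 over 2 relations), and those for diet in the cool and in the warm 0.146 (exact p = 0.159, adjusted p = 0.159). These correlations are across probes, which are not independent replicates. Over all probes the values were 0.161 (exact p = 0.1) and 0.301 (exact p = 0.018, adjusted p = 0.036), and with quantile normalization 0.193 for temperature (exact p = 0.04) and 0.198 for diet (exact p = 0.0469), both with an adjusted p of 0.0469. Whether the temperature relation passed therefore depended on the scaling.

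Females and males, 8 of each, did not differ at any probe in limma (smallest adjusted p = 0.982), and 252 probes had an unadjusted p under 0.05. The smallest p-values were those of dim probes, CUST_284_PI426386924 and CUST_523_PI426395977, which came within 0.12 and 0.42 of the floor, and CUST_161_PI426384047, whose value for females minus males was -0.67 (SE 0.150, limma adjusted p = 0.982).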

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

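In 5 of 116 groups of 4 arrays examined, over 26 named probes and the array summaries, 1 array lay so far from the other 3 that its gap to the nearest, as a share of the group's whole range, exceeded Dixon's critical value at the 95% level. Chance alone would give about 5.8 such groups, so the number is no more than chance gives. These values are listed without an explanation. For CUST_1644_PI426384047, cool control replicate 1 was at 11.844 and the other 3 arrays at 12.23 to 12.274. For CUST_191_PI426395977, warm control replicate 2 was at 6.234 and the others at 5.518 to 5.602. For CUST_107_PI426383273, cool creosote replicate 3 was at 9.836 against 9.377 to 9.435, and warm control replicate 4 at 11.449 against 12.386 to 12.561. The deposited median of warm control replicate 2 was 9.406, before scaling, and those of the other warm controls were 9.982 to 10.006.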

How the results depend on the processing

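Settings with a common lowest level, aligned background, combined choices, the floor as a covariate or the 2 arrays with the highest floor left out were added after the data were seen, as were the whole-profile shares. For the probes named by the rule fixed beforehand, each in the comparison that named it, 651 alternative values kept their direction and their side of the threshold, 154 kept the direction but no longer passed, 1 newly passed and 0 reversed. The 651 include probes that were not called and stayed so, so they do not measure how many calls held. The 154 all belong to called probes. For diet in the cool, against 274 calls, quantile normalization gave 84 (60 higher, 24 lower) and array quality weights 422. There were 0 without the dimmest 25%, with only the groups compared, a common floor at 5 or 6, or the floor covariate. Aligned background over all or the brighter probes, quantile normalization of the latter and leaving out the 2 arrays of highest floor also gave 0. Values as deposited gave 194 higher and 83 lower, against 236 and 38; on that scale the median of all probes shifted by -0.12 for diet in the cool and by -0.19 for temperature on creosote. For diet averaged over temperatures, against 217, quantile normalization gave 12 (3 higher, 9 lower) and leaving out the 2 arrays 1. Every other setting with 0 for diet in the cool that was run here also gave 0.

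For temperature on creosote, against 173, there were 96 calls with quantile normalization, 79 as deposited, 7 without the dimmest 25%, 0 with only the groups compared, 100 and 32 with a floor at 5 and 6, 839 with aligned background, 6 with aligned background and 2 with quantile normalization among the brighter probes, 72 with the floor covariate and 25 without the 2 arrays. Of the 839, 742 were lower and 97 higher, and 75 of the original 173 were among them. For temperature averaged over diets, against 156, there were 36 with quantile normalization, 18 as deposited and 17 without the dimmest 25%. A floor at 5 gave 134 (116 higher, 18 lower), and a floor at 6 gave 48. The floor covariate gave 153 (138 higher, 15 lower), 118 of them among the 156. Aligned background gave 902 (141 higher, 761 lower). Among the brighter probes, aligned background gave 5 and quantile normalization 7, and leaving out the 2 arrays gave 49 over all probes. Temperature on the control diet gave 1 call with the floor covariate, and the interaction 5 with aligned background. With fewer probes or arrays tested, lost calls follow in part from the construction. With aligned background, the many lower calls for temperature also follow in part from it, since larger constants were added to the cool creosote arrays. For the other settings the cause was not tested, apart from the floor.

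After adjustment over 6 comparisons, the shares of variance lost their call (adjusted p over 0.05) as follows. Diet in the cool lost it as deposited (27.818%), without the dimmest 25% (19.963%), with aligned background over all (28.305%) or the brighter probes (20.173%) and with a floor at 6 (20.318%). Temperature on creosote lost it in the same settings, at 23.295%, 18.213%, 38.647%, 18.102% and 19.194%. Where the exact p stayed at 0.0286, the smallest that 4 against 4 arrays can give, the loss comes from the adjustment alone: diet in the cool as deposited and with aligned background, and temperature on creosote with aligned background. Diet averaged lost it without the dimmest 25% (9.594%), with aligned background over all (10.464%) or the brighter probes (9.549%) and with a floor at 6 (9.74%). Temperature averaged lost it as deposited (11.876%), without the dimmest 25% (10.8%), with aligned background for the brighter probes (10.519%) and with a floor at 6 (11.279%).

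Leaving out each array in turn gave 0 to 325 calls for diet in the cool, 0 to 268 for diet averaged, 57 to 296 for temperature on creosote, 55 to 213 for temperature averaged, 0 to 1 for temperature on the control diet and 0 to 1 for sex. Shares ran from 30.357% to 36.481% for diet in the cool and from 22.822% to 28.185% for temperature on creosote, and both missed the adjusted threshold without cool control replicate 2 (30.713% and 23.541%) and without warm creosote replicate 2 (30.656% and 24.512%), with the exact p of 23.541% and 30.656% still at 0.0286. Calls for diet in the cool fell to 0 without cool creosote replicate 2, 66 without its replicate 3, and 21 and 135 without cool control replicates 1 and 2. Calls for diet averaged fell to 0 without cool control replicate 2, 58 without cool creosote replicate 3 and 23 without warm control replicate 1. For temperature on creosote, calls were 57, 81, 89 and 296 without cool creosote replicates 1, 2, 3 and 4, and 57 and 72 without warm creosote replicates 1 and 3. For temperature averaged they were 63 and 71 without cool control replicates 1 and 4, 99 and 100 without cool creosote replicates 1 and 2, 99, 55 and 92 without warm control replicates 1, 2 and 4, and 83 and 81 without warm creosote replicates 1 and 3.

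With the number as a replicate block, calls were 269 for diet in the cool and 234 for diet averaged. For temperature they were 157 on creosote and 179 averaged. Other comparisons had 0, and sex, which the block replaces, was not fitted. The numbers were not taken to pair the samples, since for none of the groups compared were the deviations of all 4 same-numbered pairs correlated above 0.1: 11 of 24 pairs were (-0.167 to 0.263), among them all 4 of cool creosote with warm control, and 8 of 16 arrays were closest to their own number, where 4 would be by chance. Gene lists and means over a gene's probes were not run for lack of gene names. Without background flags, no limit on signal could be tested.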

Other observations

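One probe, picked out after its values were seen, had opposite differences between the diets at the 2 temperatures. CUST_9_PI426395977 was at 10.3 ± 0.944 on creosote and 8.34 ± 0.487 on the control diet in the cool, and at 8.10 ± 0.918 and 9.50 ± 0.947 in the warm (SD, n = 4 each), an interaction of -3.33 on the log2 scale that missed the threshold (limma, unadjusted p = 0.000688, adjusted p = 0.462).

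Chosen only after the result was seen were the test of the interaction among the brighter probes, the test of how much fold change the 17 temperature probes keep, and both tests of adjacent probe numbers; the settings with the floor as a covariate and with aligned background were also added after the data were seen.

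Most probes called for diet in the cool were dim, 244 of 274. The tables argue against a change in the RNA of these probes as the whole account: with each array's floor as a covariate they kept 6.9% of their median log2 fold change, which went from 1.62 (median SE 0.329) to 0.112 (median SE 0.349), although groups and sex explain 0.719 of the variance of the floor. Within groups, the mean of these probes followed the array floor with a correlation of 0.993 over 16 arrays, against -0.158 for the brighter probes, and the floors of cool creosote and cool control arrays differed by 1.65, close to that fold change. A candidate explanation is therefore that these calls follow the lowest value each array could show. Why the floor was higher in the cool creosote arrays stays open: slide and background handling are not given in the sources used here, and an effect of the treatment on the RNA as a whole was not tested.

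Temperature called 173 probes on creosote and 0 on the control diet. A difference in background level between arrays may account for part of this. Once a constant per array aligned the 20th percentiles, 75 of the 173 probes remained called, and the median size of their fold changes went from 1.06 to 0.461. The constants were larger in cool than in warm creosote arrays and by themselves lower dim probes in the warm. The setting therefore leaves it undecided for the probes as a set. For the 17 brighter probes of the averaged comparison the values argue against an additive offset of the size added, at most 20.1 unlogged, as the whole account. They kept a median of 90.9% of their fold change (65.5% to 100.4%). Constants weigh less the brighter a probe is, so much of this was fixed by the brightness of the 17. Background differences of another size or form were not tested. Of the 17, 5 remained called, with median sizes of 0.686 before and 0.646 after, at median SEs of 0.124 and 0.121. The others had limma adjusted p up to 0.107. A coincidence of slide and temperature was not tested and stays open for all of these probes. A temperature response that differs with diet cannot be told apart from one that does not: in the fit to all probes, 195 of those outside the dimmest 25% had an unadjusted interaction p under 0.05 where 236 would be expected (220 when the brighter probes were fitted alone), and 4 arrays per group leave single interactions imprecise.

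In 1 of the 4 probe sets, that of 940 probes, probes with adjacent numbers moved together. The median correlation of their residuals was 0.526 over pairs of an odd and the next even number and 0.383 over pairs of an even and the next odd number. It was 0.053 for numbers 2 apart and 0.008 for numbers 10 apart. Numbering or position in general is argued against, since the median in the other 3 sets was at most 0.045. Whether such pairs target the same or closely similar RNA stays open: their fold changes correlated across odd-then-even pairs at 0.467 for temperature and 0.514 for diet, but across even-then-odd pairs only at 0.203 and 0.138. Where both probes were bright, median residual correlations were 0.819 and 0.757 in the 2 orders, while fold changes correlated at 0.636 for temperature and 0.748 for diet in the first order and at 0.334 and 0.195 in the second. Over all pairs, 38.8% and 32.4% in the 2 orders had a residual correlation over 0.8, so each order may mix pairs of different kinds. The lower fold correlations in the second order are therefore not read against shared targets.

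Other splits of the arrays into groups of the same sizes show how often as many probes are called. With 35 splits, 1 of 35 is the smallest share that can occur. For diet in the cool, 1 of 35 splits, the real one, called as many as 274 probes, and the highest other called 0. For temperature on creosote it was 1 of 35 (173 real, 3 for the highest other), and without the dimmest 25% of probes 1 of 35 (7 real, 6 for the highest other). For the averaged comparisons, 1 of 100 splits drawn called as many for diet (217 real, 1 for the highest other). For temperature it was also 1 of 100 (156 real, 140 for the highest other). In all of these, under 5% of the splits called as many as the real one. Called probes can move together with an array-wide quantity such as the floor. The splits cannot exclude that such a quantity fell with the groups by chance. For temperature without the dimmest 25% it was 2 of 100 (17 real), and the other split called 44, which may point to a structure of the samples beyond the groups; what the arrays of that split share was not examined. Where the real split called 0 probes, every split called as many: 35 of 35 for diet in the warm (highest other 0) and for temperature on the control diet (highest other 2), and 100 of 100 for the interaction (highest other 8) and for sex, where the highest other split called 96.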
